A study of Mus musculus with 31 samples.

How the data were processed

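RNA was sequenced from tumours of the murine mesothelioma line AB1-mCherry in untreated female BALB/c mice of 12 weeks, taken 10 days after inoculation at the subcutaneous, peritoneal or pleural site, per the labels' protocols. Whole tumours and sorted CD45-negative, mCherry-positive cells were profiled, in 31 libraries, and RNA was purified with kits that differ between the kinds of sample. Per the submitters' processing notes, the authors quantified reads with kallisto on GRCm39 and deposited TPM values per gene; the kallisto version, the annotation release, the summing of transcripts to genes and any filter are not given in the sources used here.

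The whole tumour table lists 54456 genes, 18074 of them at 0 in every library, and each library sums to 1000000. The sorted cell table lists 12461 entries, every one above 1 TPM in at least 1 library, and its libraries sum to 996124 to 998055, so low genes had been removed after TPM was computed. Calendar dates stand in place of gene symbols in 17 entries, which held 0.068 to 0.105% of TPM and were left out of all tests. Gene symbols were used as listed. Replicate numbers follow the mouse names of the labels, so peritoneal whole tumours 2, 3 and 4 are those that the table numbers 3, 4 and 5. Between 14148 and 14880 genes per whole tumour and between 11557 and 12213 per sorted library reached 1 TPM. Read numbers cannot be recovered from TPM, so the precision that depth gives is unknown.

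Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and the 3 sites of a table in 1 fit. Genes with at least 1 TPM in at least 5 libraries were tested. For each table pleural was compared with subcutaneous, peritoneal with subcutaneous, and pleural with peritoneal, and p values were adjusted over all genes of a comparison by the Benjamini-Hochberg method. Adjusted p below 0.05 was counted as a call. Tables were never tested against each other, and overlaps between them were counted over genes tested in both.

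Groups of genes came from 57 lists, fixed before the data were examined, of which 55 could be tested in whole tumours and 40 in sorted cells with at least 3 genes. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and its members were also adjusted over the list alone. Named genes were picked by rule. In each comparison these were the 8 largest positive and 8 largest negative fold changes among called genes whose groups did not overlap, with a mean of at least 5 TPM in the higher group and without predicted or clone names, up to 3 members of each called list until 30 genes were reached, and a fixed set of immune and tumour genes. In pleural against peritoneal whole tumours the rule gave fewer genes. Markers of other cell types and of neighbouring tissues were among the lists. Leukocyte RNA was compared by exact permutation of library labels.

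Alternatives were a pseudocount of 0.1, no filter, a stricter filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrial, haemoglobin and antibody genes, a fit of only the 2 sites compared, robust empirical Bayes, limma's arrayWeights, the replicate number as a block, an adjusted p below 0.01, and leaving out each library in turn. After the data were seen, fits were added without pleural tumours 3 and 5, without subcutaneous sorted libraries 1 and 2, and without peritoneal sorted libraries 2 and 5. Counts were also taken in 100 splits of the libraries, the real grouping included.

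Of 100 simulated genes changed by 1 log2 unit, 84 to 88% were recovered in whole tumours and 80 to 85% in sorted cells. Of 100 changed by 2 log2 units 95 to 97% and 97 to 98% were recovered, with 8 to 17 false calls. Data without change gave 0 called genes and lists, but regrouped libraries up to 34 lists.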

Results

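RNA profiles of the mesothelioma line AB1-mCherry, grown for 10 days at 3 sites in untreated mice, were analysed for transcripts that differ with site. The 31 libraries came from whole tumours (subcutaneous n = 5, peritoneal n = 5, pleural n = 6) and from cancer cells sorted as CD45-negative and mCherry-positive (n = 5 per site). Values are in TPM, given as mean±SD. Fold changes (log2FC) are differences of means of log2(TPM + 1), which understates the ratio for transcripts near or below 1 TPM. Whole tumours and sorted cells were normalized separately and not tested against each other. Sequencing depth is unknown.

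Among 15054 genes tested in whole tumours and 12357 in sorted cells, the first principal component held 29.1% and 33.4% of the variance, and the following component 13% and 17.4%. Pairwise correlations between libraries ranged from 0.958 to 0.991 in whole tumours and from 0.920 to 0.988 in sorted cells. The share of TPM from mitochondrial genes was 2.91 to 4.50% in peritoneal sorted cells, below the 5.6 to 6.63% of subcutaneous and the 5.13 to 6.37% of pleural sorted cells. In sorted subcutaneous replicates 1 and 2 the leukocyte transcript Ptprc (CD45) reached 12.9 and 7.5 TPM, above every other sorted library.

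**Figure D1:**
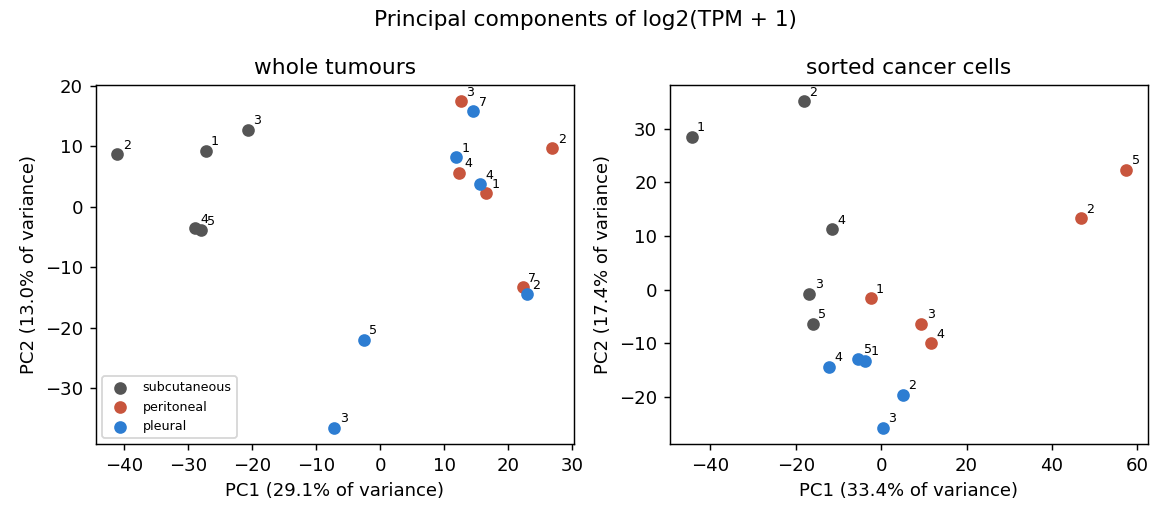
Principal components of log2(TPM + 1) for whole tumours and for sorted cancer cells, each from the genes tested in that table. Points are libraries, coloured by site of growth and numbered by replicate.

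Pleural whole tumours were first set against subcutaneous ones, and had lower transcripts of the matrix glycoproteins Tnc and Postn. Tnc, which encodes tenascin C, measured 4.32±2.58 TPM (mean ± SD, n = 6) against 119±22.5 TPM (n = 5), log2FC -4.59 (SE 0.26, adjusted p = 2.25e-08). Postn, encoding the collagen-binding protein periostin, measured 20.7±27.4 against 185±30.3 TPM (log2FC -3.78, SE 0.49, adjusted p = 0.000316), with the highest pleural value, 75.1 TPM, in replicate 3. Of the 29 matrix genes listed 4 fell and 2 rose (7 and 2 over the list alone, median log2FC -0.13, adjusted p = 0.691 with an estimated correlation), and 10 fell without pleural replicate 3. The eosinophil attractant Ccl11 fell from 40.7±10.8 to 4.71±1.79 TPM (log2FC -2.88, SE 0.21, adjusted p = 7.0e-07). The methyltransferase gene Inmt rose from 1.51±0.128 to 20.1±7.79 TPM (log2FC 2.99, SE 0.24, adjusted p = 2.33e-06). It also rose in peritoneal tumours (log2FC 3.31). For Tnc, Postn, Ccl11 and Inmt no pleural value overlapped a subcutaneous value.

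Genes of glucose breakdown were higher in pleural than in subcutaneous whole tumours. Of 16 glycolysis genes, 13 rose and 0 fell (14 and 0 when adjusted over the list alone), with a median log2FC of 0.52 and an adjusted p = 0.645 with an estimated correlation between genes. Pfkl, a phosphofructokinase subunit, rose from 49.2±12.4 to 110.2±25.8 TPM (log2FC 1.15, SE 0.18, adjusted p = 0.00121). The lactate dehydrogenase gene Ldha rose from 777±115 to 1184±176 TPM (log2FC 0.61, SE 0.11, adjusted p = 0.00475). Tpi1 (triosephosphate isomerase) rose from 568±70.0 to 848±138 TPM (log2FC 0.57, SE 0.11, adjusted p = 0.00736). Among 23 hypoxia genes 14 rose and 0 fell (14 and 0 over the list alone, median log2FC 0.70, adjusted p = 0.645 with an estimated correlation). That hypoxia count was 7 without subcutaneous replicate 1, 6 without subcutaneous replicate 2, 8 without subcutaneous replicate 4, and 7 without pleural replicate 2 or without pleural replicate 4. Car9, the hypoxia-induced carbonic anhydrase, measured 67.6±43.8 against 12.6±7.52 TPM (log2FC 2.30, SE 0.46, adjusted p = 0.00758) and stayed called with any library left out.

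Some mast cell and myeloid genes were lower in pleural whole tumours. Of 9 eosinophil and mast cell genes, 5 fell and 0 rose (6 and 0 over the list alone, median log2FC -0.90, adjusted p = 0.456 with an estimated correlation). The mast cell proteases Mcpt4, Cma1 and Tpsb2 fell to 5.77±1.65, 11.1±2.44 and 18.8±4.56 TPM from 21.6±6.66, 30.2±10.5 and 43.6±10.5 TPM (log2FCs -1.73, -1.31 and -1.17; adjusted p = 0.000219, 0.00368 and 0.00138). Among the myeloid lectins, Cd209g fell from 9.79±3.36 to 0.355±0.336 TPM (log2FC -2.95, adjusted p = 2.04e-06) and Cd209d from 4.02±1.63 to 0.272±0.181 (log2FC -1.93, adjusted p = 1.31e-05). Cd209a fell from 3.73±1.27 to 0.963±0.286 TPM (log2FC -1.23, adjusted p = 0.000795) and Clec10a from 12.8±5.44 to 4.67±2.65 TPM (log2FC -1.31, adjusted p = 0.0141). Of the 14 genes listed for type 2 and migratory dendritic cells 6 fell and 0 rose (6 and 0 over the list alone, median log2FC -0.43, adjusted p = 0.456 with an estimated correlation). That count was 2 without subcutaneous replicate 2 and 3 without subcutaneous replicate 4 or without subcutaneous replicate 5. Retnla, a product of alternatively activated macrophages, fell from 10.7±5.47 to 0.218±0.193 TPM (log2FC -3.14, adjusted p = 6.52e-06). Of 16 macrophage genes 5 fell and 0 rose (6 and 1 over the list alone, median log2FC -0.22, adjusted p = 0.645 with an estimated correlation), and the number falling ranged from 1 (without subcutaneous replicate 2) to 7 (without pleural replicate 5) with a single library left out. Of 9 alveolar macrophage genes 3 rose and 1 fell (3 and 1 over the list alone, median log2FC 0.02, adjusted p = 0.920 with an estimated correlation). Ptprc did not pass (52.6±13.5 against 57.5±13.7 TPM, log2FC -0.13, adjusted p = 0.690).

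Some chemokine and tissue genes also differed between pleural and subcutaneous whole tumours. Of 30 chemokine genes 7 fell and 1 rose (8 and 1 over the list alone, median log2FC -0.28, adjusted p = 0.534 with an estimated correlation). Without subcutaneous replicate 2 the number falling was 3. Besides Ccl11, the platelet factor gene Pf4 fell to 12.4±4.69 from 51.5±28.9 TPM (log2FC -1.89, adjusted p = 0.00297) and Cxcl14 to 76.6±59.8 from 206±39.2 TPM (log2FC -1.68, adjusted p = 0.00983). Mesothelial genes were higher, with 8 of 19 rising and 0 falling (11 and 0 over the list alone, median log2FC 0.74, adjusted p = 0.534 with an estimated correlation). The serosal transcription factor Gata6 rose from 2.21±0.300 to 3.70±1.05 TPM (log2FC 0.53, adjusted p = 0.0192). Of 18 skeletal muscle genes 9 fell and 0 rose (14 and 0 over the list alone, median log2FC -2.21, adjusted p = 0.534 with an estimated correlation). Only 1 fell without subcutaneous replicate 2 and 4 without pleural replicate 2. Pleural replicates 3 and 5 also held muscle RNA, and without both libraries 12 of 13 tested muscle genes fell. Tnnc2 (fast troponin C, log2FC -4.05, adjusted p = 0.0173) and Pvalb (parvalbumin, log2FC -2.22, adjusted p = 0.0194) lost their calls without subcutaneous replicate 2 (adjusted p = 0.0566 and 0.0536). The fast myosin gene Myh4 kept its call (log2FC -3.29, adjusted p = 0.00276).

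The remaining large changes of this comparison included antibody genes, which plasma cells express. Of 11 plasma cell genes 4 rose and 1 fell (4 and 1 over the list alone, median log2FC 0.46, adjusted p = 0.728 with an estimated correlation). Igkc, the kappa constant region, rose from 40.3±19.5 to 383±269.7 TPM (log2FC 3.03, SE 0.62, adjusted p = 0.00818). The joining chain gene Jchain rose from 3.85±1.85 to 34.4±22.4 TPM (log2FC 2.68, SE 0.56, adjusted p = 0.00903). The segments Igkv3-7, Igkv6-23 and Iglv1 also rose (log2FCs 2.87, 2.87 and 2.57; adjusted p = 0.00103, 0.0189 and 0.0145). An Igkv16 segment was called too (log2FC 2.29, adjusted p = 0.0405) but failed in 13 alternative fits. Thbs4 (thrombospondin 4) fell from 27.1±10.4 to 3.83±4.85 TPM (log2FC -2.94, adjusted p = 0.00259). Crabp1, a retinoic acid binding protein, fell from 33.5±16.9 to 0.330±0.225 TPM (log2FC -4.57, adjusted p = 1.74e-08). The urinary protein gene Mup10 fell from 46.6±32.7 to 0.155±0.378 TPM (log2FC -4.79, adjusted p = 0.000315). Zfp969 was listed at 0 in all pleural tumours against 10.4±8.24 TPM. Mup genes and antibody variable segments have close paralogs, so which family member the reads came from is uncertain.

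In total 1927 genes passed between pleural and subcutaneous whole tumours, 1415 higher and 512 lower, and 187 of them changed at least 2-fold (81 higher, 106 lower). Over all 15054 tested genes the groups did not overlap in 1168, where chance gives 0.433% of genes. With a single library left out the number fell to 748 without subcutaneous replicate 2, to 1049 without pleural replicate 2 and to 1272 without pleural replicate 4. The 2-fold number fell to 119 without subcutaneous replicate 2. The excess of higher genes depended on scaling: 73.4% were higher as measured, against 46.0% (721 higher, 845 lower) with median-of-ratios and 48.4% (674 and 718) with quantile scaling. In 100 splits of the libraries, the real grouping included, no other split called more than 191 genes. The number of gene lists called was at least as high as the real one in 28 of the 100, the real one included, so list calls are described here only through their members.

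Peritoneal whole tumours, compared with subcutaneous ones, had higher values of mesothelial genes. Of 19 mesothelial genes 16 rose and 0 fell (17 and 0 over the list alone, median log2FC 1.20), with the smallest list value of the study, adjusted p = 0.170 with an estimated correlation. Wt1, a transcription factor of mesothelium, rose from 0.728±0.289 to 3.85±0.428 TPM (n = 5 each, log2FC 1.50, SE 0.18, adjusted p = 0.000111). Aldh1a2, which makes retinoic acid, rose from 5.93±3.18 to 33.9±5.67 TPM (log2FC 2.43, SE 0.35, adjusted p = 0.000698), and Lrrn4, a mesothelial surface gene, from 0.0451±0.0191 to 2.21±0.761 TPM (log2FC 1.59, SE 0.20, adjusted p = 0.000256). Gata6 rose from 2.21±0.300 to 3.86±0.493 TPM (log2FC 0.60, adjusted p = 0.0134). No preset list call held with an estimated correlation in any comparison of the study.

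Some macrophage and natural killer markers fell in peritoneal whole tumours, and some B and plasma cell genes rose. Of 16 macrophage genes 8 fell and 0 rose (10 and 0 over the list alone, median log2FC -0.68, adjusted p = 0.404 with an estimated correlation). The scavenger receptor Cd163 fell from 8.20±3.65 to 2.14±0.369 TPM (log2FC -1.44, adjusted p = 0.00917) and the mannose receptor Mrc1 from 41.4±12.5 to 19.2±2.68 (log2FC -1.02, adjusted p = 0.0108). Trem2, a lipid receptor, fell from 58.2±6.22 to 40.7±1.55 TPM (log2FC -0.50, adjusted p = 0.00580). That count was 4 without subcutaneous replicate 2, and 5 without subcutaneous replicate 4, without subcutaneous replicate 5, or without any single library of peritoneal replicates 1, 2 and 3. Among 10 natural killer genes 5 fell and 0 rose (9 and 0 over the list alone, median log2FC -0.75, adjusted p = 0.404 with an estimated correlation). Only 3 fell without any single library of subcutaneous replicates 1, 3, 4 and 5 or of peritoneal replicates 1, 2 and 3. The activating receptor Ncr1 fell from 11.9±2.26 to 3.73±1.11 TPM (log2FC -1.46, adjusted p = 0.00300) and the granule protease Gzma from 31.7±4.58 to 10.8±3.56 TPM (log2FC -1.52, adjusted p = 0.00529). The lectin receptor Klrb1c fell from 2.16±0.964 to 0.628±0.183 TPM (log2FC -0.91, adjusted p = 0.00914). Of 12 pan-leukocyte genes 2 fell and 0 rose (4 and 0 over the list alone, median log2FC -0.39, adjusted p = 0.481 with an estimated correlation). These were Cd53 (log2FC -0.64, adjusted p = 0.0152) and Laptm5 (log2FC -0.42, adjusted p = 0.0396), the latter failing in 10 alternative fits. Ptprc did not pass (41.0±11.8 against 57.5±13.7 TPM, log2FC -0.48, adjusted p = 0.126) but passed without peritoneal replicate 7 (log2FC -0.64, adjusted p = 0.0480).

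Some chemokine genes fell too in peritoneal whole tumours. Of 30, 10 fell and 1 rose (13 and 2 over the list alone, median log2FC -0.57, adjusted p = 0.404 with an estimated correlation). The number falling was 5 without subcutaneous replicate 2 or without peritoneal replicate 2, 4 without subcutaneous replicate 5 or without peritoneal replicate 3, and 6 without subcutaneous replicate 4 or without pleural replicate 4. Ccl11 fell from 40.7±10.8 to 13.6±2.19 TPM (log2FC -1.48, adjusted p = 0.000937) and Cxcl14 from 206±39.2 to 49.6±16 TPM (log2FC -2.06, adjusted p = 0.00387). The membrane-bound chemokine Cxcl16 fell from 107±16.6 to 56.8±14.7 TPM (log2FC -0.93, adjusted p = 0.00502). Of 34 cell cycle genes 11 rose and 0 fell (19 and 0 over the list alone, median log2FC 0.15, adjusted p = 0.481 with an estimated correlation). That number was as low as 4, without subcutaneous replicate 2, without peritoneal replicate 1 or without peritoneal replicate 3.

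Muscle and antibody transcripts gave the largest folds of the named genes between peritoneal and subcutaneous whole tumours. Of 18 skeletal muscle genes 14 fell and 0 rose (15 and 0 over the list alone, median log2FC -2.95, adjusted p = 0.404 with an estimated correlation). Of these 7 fell without subcutaneous replicate 2, 9 without subcutaneous replicate 4 or without peritoneal replicate 2. The skeletal actin gene Acta1 fell from 182±143 to 0.191±0.0998 TPM (log2FC -6.75, SE 1.27, adjusted p = 0.00478). Tnnc2 (log2FC -5.16, adjusted p = 0.00645) and the fast troponin Tnnt3 (log2FC -4.31, adjusted p = 0.0105) fell as well, and Myh4 was listed at 0 in all peritoneal tumours. The myosin light chain gene Myl1 (log2FC -5.06, adjusted p = 0.0219) and the creatine kinase gene Ckm (log2FC -4.78, adjusted p = 0.0181) lost their calls without subcutaneous replicate 2 (adjusted p = 0.0607 and 0.0524). Igkc rose from 40.3±19.5 to 859.5±748 TPM (log2FC 4.06, SE 0.65, adjusted p = 0.00154) and Jchain from 3.85±1.85 to 79.1±63.9 TPM (log2FC 3.70, SE 0.59, adjusted p = 0.00151). Of 11 plasma cell genes 5 rose and 1 fell (8 and 1 over the list alone, median log2FC 0.83, adjusted p = 0.481 with an estimated correlation). The number of plasma cell genes rising was 3 without any single library of subcutaneous replicates 2, 3, 4 and 5 or without peritoneal replicate 2. Of 11 B cell genes 3 rose and 0 fell (7 and 0 over the list alone, median log2FC 1.18, adjusted p = 0.630 with an estimated correlation). That B cell number was 0 without subcutaneous replicate 2 or without peritoneal replicate 2, 1 without subcutaneous replicate 3, 4 or 5 singly, and 5 without peritoneal replicate 3, without peritoneal replicate 4 or without pleural replicate 2. The segments Igkv4-53, Igkv1-88, Igkv4-91 and Iglv1 rose by log2FCs of 5.82, 4.72, 3.40 and 3.34 (adjusted p = 0.00851, 0.0110, 0.0176 and 0.00470), and an Igkv14 segment by 3.72 (adjusted p = 0.00567). Ighg1 was called (log2FC 3.74, adjusted p = 0.0482) but failed in 15 alternative fits. Crabp1 (log2FC -4.85, adjusted p = 1.80e-08), Mup10 (log2FC -4.80, adjusted p = 0.000380) and Mup22 (log2FC -4.53, adjusted p = 0.00240) were lower. The same uncertainty about paralogs holds here.

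Altogether 1831 genes passed between peritoneal and subcutaneous whole tumours, 1283 higher and 548 lower, with 266 at 2-fold or more (132 higher, 134 lower). Over all 15054 tested genes the groups did not overlap in 1888, where chance gives 0.794% of genes. Leaving out a single library moved the number to 896 without subcutaneous replicate 2, 985 without peritoneal replicate 2, 1112 without subcutaneous replicate 5, 1141 without peritoneal replicate 1 and 1200 without peritoneal replicate 3. Of the called genes 70.1% were higher as measured, against 45.5% (708 higher, 849 lower) with median-of-ratios and 48.2% (729 and 782) with quantile scaling. Among 100 splits of the libraries, the real grouping included, the highest number of called genes in any other split was 4.

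The serosal sites shared much of their difference from the subcutaneous site. In whole tumours 944 genes were called against the subcutaneous group in both comparisons and in the same direction, 665 higher and 279 lower, including Igkc, Jchain, Gata6, Ccl11, Cxcl14, Tnnc2, Crabp1 and Mup10. In opposite directions 0 were called. The shared subcutaneous libraries raise such an overlap. Fold changes correlated with r = 0.83, against 0.52 in simulated data without site effects. Separate references of fewer subcutaneous libraries gave 72 to 203 shared genes. The number was 361 without subcutaneous replicate 2, 578 without subcutaneous replicate 5 and 629 without peritoneal replicate 1. In sorted cells the number was 155 (r = 0.61, simulated 0.50), 25 higher, 130 lower and 0 opposite. They included Inmt, Car9, Calcb, Postn, Tnc, Cxcl14, Ccl11 and Thy1. Splitting the reference gave 54 to 139, and the number was 99 without subcutaneous replicate 1, 103 without subcutaneous replicate 2 and 64 without both.

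Between pleural and peritoneal whole tumours few genes passed. Ccn2, a target of YAP and TGF-beta signalling, measured 137±27.7 TPM (n = 6) in pleural and 73.1±7.14 TPM (n = 5) in peritoneal tumours (log2FC 0.88, SE 0.15, adjusted p = 0.0455). The transcriptional repressor Bcl6 (18.6±1.54 against 12.2±1.30 TPM, log2FC 0.57, adjusted p = 0.0455) and the kinase gene Plk2 (43.7±2.18 against 33.9±1.53 TPM, log2FC 0.36, adjusted p = 0.0455) were higher too. Ccl11 was lower (4.71±1.79 against 13.6±2.19 TPM, log2FC -1.40, adjusted p = 0.0435). Without peritoneal replicate 2 none of the 4 passed (adjusted p = 0.188, 0.173, 0.188 and 0.133). Of the 19 mesothelial genes 0 passed over all genes and 7 fell when adjusted over the list alone (median log2FC -0.39, adjusted p = 0.410 with an estimated correlation).

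Only 8 genes passed in that comparison, 4 higher and 4 lower, of which 4 changed at least 2-fold, and limma gave 1673 genes with unadjusted p < 0.05. The number ranged from 0 to 33 with a single library left out, the highest without pleural replicate 3. Across 100 splits of the libraries 8 was reached in 2, the real grouping included, so the number is no larger than the highest found by regrouping.

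Of the single checkpoint and lymphocyte genes chosen in advance, Cd8a, Foxp3, Pdcd1 and Cd274 did not pass in whole tumours and Ctla4 passed in peritoneal against subcutaneous tumours. The cytotoxic coreceptor Cd8a measured 13.6±4.02 TPM in pleural (n = 6), 13.7±2.75 in peritoneal (n = 5) and 14.3±3.40 in subcutaneous tumours (n = 5), and did not pass in any comparison (adjusted p = 0.801, 0.928 and 0.941). Foxp3 of regulatory T cells (adjusted p = 0.118 and 0.110 against the subcutaneous group, 0.963 between serosal sites), the inhibitory receptor Pdcd1 (adjusted p = 0.534, 0.393 and 0.399) and its ligand Cd274 (adjusted p = 0.704, 0.706 and 0.652) also did not pass. Ctla4, a further inhibitory receptor, fell in peritoneal tumours to 2.06±0.787 from 3.91±1.17 TPM (log2FC -0.69, SE 0.18, adjusted p = 0.0267). That call was lost without subcutaneous replicate 4 (adjusted p = 0.0589), subcutaneous replicate 5 (0.0658) or peritoneal replicate 1 (0.0553), 2 (0.0708) or 3 (0.0622). In pleural tumours Ctla4 did not pass (2.46±0.558 TPM, log2FC -0.49, adjusted p = 0.0751). In peritoneal against subcutaneous tumours 5 of 12 cytotoxic genes, Gzma among them, fell and 0 rose (5 and 0 over the list alone, median log2FC -0.42, adjusted p = 0.424 with an estimated correlation). So did 4 of 9 genes of CD4 and regulatory T cells (5 over the list alone, median log2FC -0.43, adjusted p = 0.424 with an estimated correlation). Those numbers were 3 and 2 without any single library of subcutaneous replicates 4 and 5 or of peritoneal replicates 1, 2 and 3, and 3 cytotoxic genes fell without subcutaneous replicate 3. Of 21 immune checkpoint genes 3 fell and 1 rose in that comparison (3 and 1 over the list alone, median log2FC -0.24, adjusted p = 0.489 with an estimated correlation). The tumour antigen gene Msln (mesothelin) did not pass in whole tumours (adjusted p = 0.455, 0.448 and 0.390). It was called between pleural and subcutaneous tumours without pleural replicates 3 and 5 (log2FC 0.36, adjusted p = 0.0128).

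Total leukocyte RNA was tested separately by exact permutation. In whole tumours Ptprc differed by log2FCs of -0.13 (pleural against subcutaneous, exact permutation p = 0.543), -0.48 (peritoneal against subcutaneous, p = 0.0794) and 0.36 (pleural against peritoneal, p = 0.130). The mean of 12 pan-leukocyte genes gave -0.19 (exact permutation p = 0.199), -0.36 (p = 0.0714) and 0.17 (p = 0.342), and the smallest value adjusted over the 12 tests was 0.310. None of the leukocyte differences passed.

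**Figure D2:**
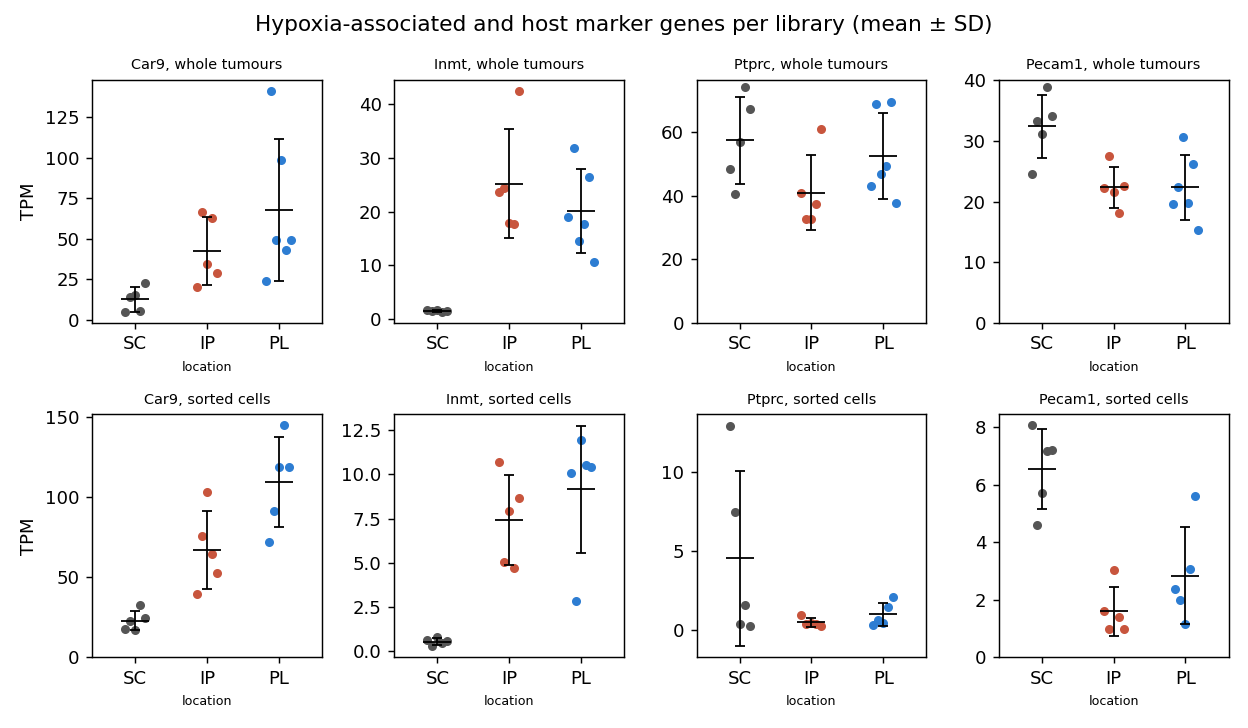
Values of Car9, Inmt, Ptprc and Pecam1 in whole tumours and sorted cancer cells at the subcutaneous (SC), peritoneal (IP) and pleural (PL) site. Bars are means with SD and dots are libraries, in TPM.

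Pleural sorted cells were compared with subcutaneous ones. Host stroma in the latter stays open (endothelial Pecam1 6.56 against 2.84 TPM). The matrix genes Postn and Tnc fell in pleural cells too. Postn measured 1.43±1.03 against 92.2±37.1 TPM (mean ± SD, n = 5 each, log2FC -5.29, SE 0.34, adjusted p = 4.51e-07). Tnc measured 1.09±0.557 against 56.9±22 TPM (log2FC -4.77, SE 0.29, adjusted p = 2.93e-07). Of 29 matrix genes 9 fell and 0 rose (10 and 0 over the list alone, median log2FC -0.28, adjusted p = 0.473 with an estimated correlation). The collagen crosslinker Loxl2 was among them (0.661±0.299 against 6.99±2.48 TPM, log2FC -2.23, adjusted p = 2.83e-05). The matrix proteases Mmp2 (2.41±0.988 against 28.0±11.5 TPM, log2FC -3.07, adjusted p = 1.22e-05) and Mmp3 (0.602±0.259 against 13.2±10.7 TPM, log2FC -2.93, adjusted p = 2.83e-05) fell. The carboxypeptidase-like Cpxm1 (log2FC -3.64, adjusted p = 2.62e-06) and the cartilage layer protein Cilp (log2FC -3.20, adjusted p = 1.82e-06) fell as well. Without subcutaneous replicates 1 and 2, which held leukocyte RNA, 7 matrix genes still fell.

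**Figure D3:**
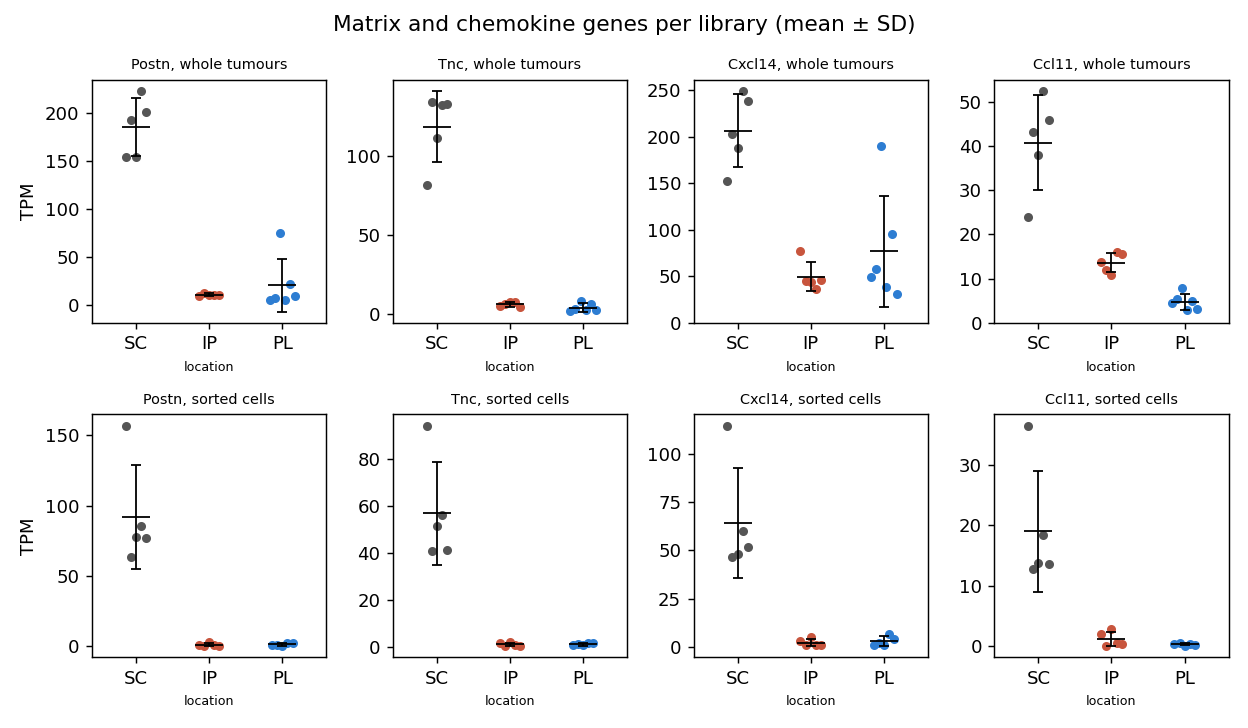
Postn, Tnc, Cxcl14 and Ccl11 in whole tumours and sorted cancer cells at the 3 sites. Bars are means with SD and dots are libraries, in TPM.

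Part of the chemokine, fibroblast and endothelial genes fell beside the matrix genes in pleural sorted cells. Of 23 chemokine genes 6 fell and 0 rose (9 and 0 over the list alone, median log2FC -0.93, adjusted p = 0.346 with an estimated correlation). Cxcl14 fell from 64.4±28.8 to 2.85±2.43 TPM (log2FC -4.21, SE 0.43, adjusted p = 2.30e-05) and Ccl11 from 19.0±10.0 to 0.347±0.199 TPM (log2FC -3.79, SE 0.33, adjusted p = 6.54e-06). The stromal chemokine Cxcl12 fell from 10.3±4.37 to 1.19±0.651 TPM (log2FC -2.34, adjusted p = 9.98e-05). Of 13 fibroblast genes 5 fell and 0 rose (7 and 0 over the list alone, median log2FC -0.50, adjusted p = 0.346 with an estimated correlation). Among them were the microfibril gene Mfap5 at 28.7±3.94 against 88.3±21.2 TPM (log2FC -1.57, adjusted p = 6.54e-06) and the fibroblast gene Pi16 at 0.929±0.5 against 4.09±1.38 TPM (log2FC -1.41, adjusted p = 0.00304). The surface glycoprotein Thy1 fell from 45.8±19.3 to 2.74±0.610 TPM (log2FC -3.57, adjusted p = 2.83e-05). Of 9 endothelial genes 4 fell and 0 rose (9 and 0 over the list alone, median log2FC -1.06, adjusted p = 0.346 with an estimated correlation). That endothelial count ranged from 1 to 7 with a single library left out. Emcn, Eng and Plvap (log2FCs -1.13, -0.90 and -1.31; adjusted p = 0.0140, 0.0287 and 0.0442) lost their calls without subcutaneous replicates 1 and 2. The leukocyte gene Cd53 fell from 18.9±12.2 to 2.01±0.850 TPM (log2FC -2.58, adjusted p = 0.000129). Ptprc did not pass (0.963±0.754 against 4.51±5.57 TPM, log2FC -0.90, adjusted p = 0.614).

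Higher in pleural sorted cells were Car9, at 109±28.1 against 23±6.14 TPM (log2FC 2.20, SE 0.24, adjusted p = 5.67e-05), and Inmt, at 9.15±3.61 against 0.538±0.192 TPM (log2FC 2.61, SE 0.29, adjusted p = 6.45e-05). The neuropeptide gene Calcb (9.97±3.45 against 2.41±0.781 TPM, log2FC 1.64, adjusted p = 0.00154) and Adam22, a synaptic receptor gene (13.3±4.26 against 3.69±0.721 TPM, log2FC 1.57, adjusted p = 0.000928) were higher as well. Of 16 glycolysis genes 4 rose and 1 fell (11 and 1 over the list alone, median log2FC 0.40, adjusted p = 0.346 with an estimated correlation). The number rising ranged from 0 to 8 with a single library left out and was 0 without subcutaneous replicates 1 and 2. The enzymes Aldoa, Eno1 and Gpi1 (log2FCs 0.48, 0.46 and 0.50; adjusted p = 0.0191, 0.0426 and 0.0442) lost their calls without those libraries, as did Ccn2 (298±254 against 68.1±18.6 TPM, log2FC 1.81, adjusted p = 0.0204). Also lost without them were the keratin gene Krt8 (log2FC -2.15, adjusted p = 0.0300), the complement inhibitor Serping1 (log2FC -1.61, adjusted p = 0.00876) and the olfactory receptor Olfr1217 (log2FC 1.21, adjusted p = 0.0106), whose family assignment is uncertain. Haemoglobin transcripts moved too. Hbb-bs measured 68.6±80.1 against 4.04±1.73 TPM (log2FC 3.21, adjusted p = 0.0132) and Hba-a1 54.1±63.2 against 4.84±2.99 TPM (log2FC 2.80, adjusted p = 0.0305), both lost without subcutaneous replicates 1 and 2. Crabp1 fell from 11.2±6.37 to 0.0630±0.0490 TPM (log2FC -3.35, adjusted p = 5.10e-06).

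A total of 203 genes passed between pleural and subcutaneous sorted cells, 49 higher and 154 lower, with 118 at 2-fold or more (20 higher, 98 lower). Over all 12357 tested genes the groups did not overlap in 384, against a chance share of 0.794%. The share of higher genes was 24.1% as measured and 39.7% (106 higher, 161 lower) with quantile scaling. With a single library left out the number was lowest without subcutaneous replicate 2 (118), without subcutaneous replicate 1 (120) and without subcutaneous replicate 3 (133). Without both subcutaneous replicates 1 and 2 (chosen after the data were seen) 70 genes passed, 56 of them at least 2-fold. Other splits, made with all libraries, gave at most 60 against the 203.

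Peritoneal sorted cells differed from subcutaneous ones in the same matrix genes. Postn measured 1.10±1.15 against 92.2±37.1 TPM (mean ± SD, n = 5 each, log2FC -5.54, SE 0.34, adjusted p = 1.92e-07). Tnc measured 0.967±0.812 against 56.9±22 TPM (log2FC -4.91, SE 0.29, adjusted p = 1.90e-07) and Loxl2 0.660±0.524 against 6.99±2.48 TPM (log2FC -2.27, adjusted p = 1.63e-05). Timp3, a matrix-bound protease inhibitor, fell from 21.5±10.9 to 0.778±0.722 TPM (log2FC -3.63, adjusted p = 2.81e-06) and Cilp from 18.6±9.67 to 0.367±0.166 (log2FC -3.73, adjusted p = 1.92e-07). Cpxm1 fell from 24.5±13.3 to 1.07±0.768 (log2FC -3.58, adjusted p = 2.43e-06) and Thy1 from 45.8±19.3 to 4.11±3.37 TPM (log2FC -3.35, adjusted p = 3.38e-05). Of 29 matrix genes 17 fell and 0 rose (21 and 0 over the list alone, median log2FC -0.58, adjusted p = 0.290 with an estimated correlation). Only 10 fell without subcutaneous replicate 1 or without peritoneal replicate 2 and 11 without subcutaneous replicate 3. Of 23 chemokine genes 11 fell and 0 rose (13 and 0 over the list alone, median log2FC -1.78, adjusted p = 0.290 with an estimated correlation). These included Cxcl14 at 2.03±1.94 (log2FC -4.55, adjusted p = 7.91e-06), Ccl11 at 1.16±1.17 (log2FC -3.26, adjusted p = 1.59e-05) and Cxcl12 at 0.643±0.596 TPM (log2FC -2.78, adjusted p = 1.26e-05). Of 13 fibroblast genes 6 fell and 0 rose (9 and 0 over the list alone, median log2FC -0.76, adjusted p = 0.290 with an estimated correlation). Endothelial genes moved with them, 8 of 9 falling and 0 rising (8 and 0 over the list alone, median log2FC -1.57, adjusted p = 0.290 with an estimated correlation). Examples are Emcn (log2FC -1.63, adjusted p = 0.000343), Eng (log2FC -1.26, adjusted p = 0.00102) and Flt1 (log2FC -0.99, adjusted p = 0.00178). Crabp1 was listed at 0 in all peritoneal sorted cells against 11.2±6.37 TPM.

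Genes of sterol synthesis were lower in peritoneal sorted cells. Of 20 cholesterol genes 12 fell and 0 rose (15 and 0 over the list alone, median log2FC -0.53, adjusted p = 0.290 with an estimated correlation). The mevalonate gene Hmgcs1 fell from 181±61.2 to 64.7±24.9 TPM (log2FC -1.47, SE 0.25, adjusted p = 0.00181). The prenyl synthase Fdps fell from 382±42.2 to 261±32.9 TPM (log2FC -0.55, SE 0.10, adjusted p = 0.00261). The retinal reductase Dhrs3 rose to 66.6±8.66 against 14.6±3.52 TPM (log2FC 2.14, SE 0.22, adjusted p = 1.71e-05). The retinol importer Stra6 measured 24.4±4.68 against 9.19±2.91 TPM (log2FC 1.35, SE 0.21, adjusted p = 0.00112). Of 11 listed retinoid genes 4 rose and 3 fell (4 and 4 over the list alone, median log2FC -0.09, adjusted p = 0.940 with an estimated correlation). Car9 rose to 67.1±24.2 (log2FC 1.47, SE 0.24, adjusted p = 0.00155), but 4 of 21 hypoxia genes fell. Inmt rose to 7.40±2.54 (log2FC 2.40, SE 0.29, adjusted p = 0.000103) and Calcb to 8.28±1.93 TPM (log2FC 1.45, adjusted p = 0.00229). The casein gene Csn3 (log2FC 1.58, adjusted p = 0.000313) and the fatty acid ligase Acsm3 (log2FC 1.30, adjusted p = 0.00835) rose too. The adhesion gene Selp (log2FC 1.32, adjusted p = 0.0137) rose but lost its call without subcutaneous replicates 1 and 2.

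Some cell cycle, interferon, immediate early and TGF-beta response genes also differed between peritoneal and subcutaneous sorted cells. Cdc20, an activator of the anaphase complex, rose from 72.0±7.91 to 123±16.4 TPM (log2FC 0.76, SE 0.10, adjusted p = 0.000318). The mitotic kinase Plk1 rose from 32.4±4.52 to 51.3±4.99 TPM (log2FC 0.65, SE 0.11, adjusted p = 0.00187) and the replication helicase gene Mcm3 from 87.7±5.36 to 119±11.6 TPM (log2FC 0.43, SE 0.09, adjusted p = 0.00584). Of 34 cell cycle genes 10 rose and 0 fell (14 and 0 over the list alone, median log2FC 0.27, adjusted p = 0.351 with an estimated correlation). That was 5 without subcutaneous replicate 4, without subcutaneous replicate 5 or without peritoneal replicate 2, and 6 without subcutaneous replicate 1 or without peritoneal replicate 5. Of 25 type I interferon genes 11 fell and 0 rose (19 and 0 over the list alone, median log2FC -0.90, adjusted p = 0.454 with an estimated correlation). Among them were the antiviral genes Rsad2 (log2FC -1.33, adjusted p = 0.00460) and Oasl1 (log2FC -0.89, adjusted p = 0.00920) and the regulator Irf7 (29.8±5.33 against 63.5±18.1 TPM, log2FC -1.05, adjusted p = 0.00808). Only 7 fell without subcutaneous replicate 1 and 6 without peritoneal replicate 2. In pleural sorted cells 0 of these 25 passed over all genes and 15 fell over the list alone (median log2FC -0.78, adjusted p = 0.473 with an estimated correlation). Of 24 immediate early and heat shock genes 9 fell and 0 rose in peritoneal cells (12 and 0 over the list alone, median log2FC -0.80, adjusted p = 0.454 with an estimated correlation), or 15 without subcutaneous replicate 2. Among 19 TGF-beta response genes 10 fell and 0 rose (12 and 0 over the list alone, median log2FC -0.91, adjusted p = 0.290 with an estimated correlation), and 6 without subcutaneous replicate 1 or without peritoneal replicate 2. Without both subcutaneous replicates 1 and 2, which held leukocyte RNA, 6 cell cycle genes rose and 3 interferon, 15 immediate early and 6 TGF-beta response genes fell. Without both peritoneal replicates 2 and 5 these numbers were 6, 5, 5 and 5. Peritoneal cells also had the lower mitochondrial share given above.

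In all 1369 genes passed between peritoneal and subcutaneous sorted cells, 587 higher and 782 lower, of which 317 changed at least 2-fold (36 higher, 281 lower). Over all 12357 tested genes the groups did not overlap in 1171, against a chance share of 0.794%. The share of higher genes was 42.9% as measured, 61.3% (1525 higher, 961 lower) with quantile scaling, and 31.7% (421 and 905) when mitochondrial, haemoglobin and antibody genes were removed before rescaling, so the balance of directions is not determined. Leaving out single libraries moved the number to 752 without subcutaneous replicate 5, 754 without peritoneal replicate 2 and 806 without subcutaneous replicate 1. Without both peritoneal replicates 2 and 5, left out after the data were seen, it was 741 (204 at least 2-fold). At most 165 were called in other splits.

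More genes passed between pleural and peritoneal sorted cells than between the whole tumours, with sterol genes higher in pleural cells. Of 20 cholesterol genes 13 rose and 0 fell (17 and 0 over the list alone, median log2FC 0.64, adjusted p = 0.343 with an estimated correlation). The squalene epoxidase gene Sqle measured 109.6±19.9 against 65.1±6.31 TPM (mean ± SD, n = 5 each, log2FC 0.73, SE 0.13, adjusted p = 0.00545) and the sterol desaturase gene Sc5d 36.3±5.23 against 22.8±2.48 TPM (log2FC 0.64, adjusted p = 0.00482). Cell cycle genes were lower, 17 of 34 falling and 0 rising (18 falling and 1 rising over the list alone, median log2FC -0.32, adjusted p = 0.572 with an estimated correlation). Plk1 was at 27.0±3.41 against 51.3±4.99 TPM (log2FC -0.90, SE 0.11, adjusted p = 0.000653) and Cdc20 at 68.8±7.24 against 123±16.4 TPM (log2FC -0.82, adjusted p = 0.000774). The ubiquitin ligase partner Ube2c was at 109±6.66 against 184±28.1 TPM (log2FC -0.73, adjusted p = 0.000774). Dhrs3 was lower in pleural cells (24.5±9.63 against 66.6±8.66 TPM, log2FC -1.48, adjusted p = 0.00272).

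Sgk1, Dusp5 and some immediate early genes were higher in pleural than in peritoneal sorted cells. Handling during sorting stays open. The kinase gene Sgk1 measured 101±59.8 against 11.5±6.37 TPM (log2FC 2.97, SE 0.46, adjusted p = 0.00323), and the phosphatase gene Dusp5 98.5±49.9 against 16.2±7.73 TPM (log2FC 2.48, SE 0.42, adjusted p = 0.00463). The neutrophil attractants Cxcl1 and Cxcl2 measured 851±216 and 146±55.9 against 193±155 and 30.8±27.1 TPM (log2FCs 2.41 and 2.46; adjusted p = 0.00960 and 0.00703). Of 24 immediate early and heat shock genes 8 rose and 0 fell (11 and 0 over the list alone, median log2FC 1.05, adjusted p = 0.572 with an estimated correlation). Egr1 was at 1535±128 against 732±187 TPM (log2FC 1.10, SE 0.21, adjusted p = 0.00795) and Ier3 at 319±46.1 against 105±50.2 TPM (log2FC 1.69, adjusted p = 0.00475). That number was 13 without subcutaneous replicate 2 and 5 without peritoneal replicate 2 or 5 or pleural replicate 1, 2 or 5 singly. Of 25 TNF response genes 7 rose and 0 fell (11 and 0 over the list alone, median log2FC 0.57, adjusted p = 0.572 with an estimated correlation), or 11 without peritoneal replicate 3. Of 19 TGF-beta response genes 8 rose and 0 fell (10 and 0 over the list alone, median log2FC 0.65, adjusted p = 0.572 with an estimated correlation), or 4 without peritoneal replicate 2. Skil (log2FC 1.74, adjusted p = 0.0103) and Ccn2 (log2FC 1.76, adjusted p = 0.0128) were among them. Of 21 hypoxia genes 6 rose and 0 fell (15 and 0 over the list alone, median log2FC 0.57, adjusted p = 0.572 with an estimated correlation). An example is the pyruvate dehydrogenase kinase Pdk1 (53.2±8.30 against 27.7±8.77 TPM, log2FC 0.97, adjusted p = 0.0110). The number was 2 without peritoneal replicate 2, 3 without peritoneal or pleural replicate 5, 10 without subcutaneous replicate 4 and 13 without peritoneal replicate 3. Tnfaip3, Nr4a3, Egr2, Egln1, Bhlhe40 and Smad7 were called (log2FCs 2.47, 2.45, 1.76, 0.45, 1.20 and 1.71; adjusted p = 0.0151, 0.00925, 0.0106, 0.0185, 0.0190 and 0.0110) but not without peritoneal replicates 2 and 5. Of 24 genes of the unfolded protein and integrated stress response 4 fell and 2 rose (4 and 3 over the list alone, median log2FC 0.04, adjusted p = 0.932 with an estimated correlation).

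Mitochondrial transcripts were also higher in pleural than in peritoneal sorted cells. The complex I gene mt-Nd3 measured 968±204 against 146±114 TPM (log2FC 3.02, SE 0.37, adjusted p = 0.000653). The ribosomal mt-Rnr2 measured 237±75.8 against 37.1±8.38 TPM (log2FC 2.62, SE 0.22, adjusted p = 3.60e-05). Lower in pleural cells were the actin-binding gene Avil (log2FC -1.60, adjusted p = 0.0152), the costimulatory receptor Tnfrsf4 (log2FC -1.42, adjusted p = 0.00925) and Sncg (log2FC -1.30, adjusted p = 0.00573). Bcl2l15 (log2FC -1.22, adjusted p = 0.000935) and Anxa8 (log2FC -1.20, adjusted p = 0.0103) were lower as well, whereas Krt8 (log2FC -1.87, adjusted p = 0.0259) and Selp (log2FC -1.29, adjusted p = 0.0198) lost their calls without peritoneal replicate 2.

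Between pleural and peritoneal sorted cells 1231 genes passed, 550 higher and 681 lower, 152 of them by at least 2-fold (128 higher, 24 lower). Over all 12357 tested genes the groups did not overlap in 1182, against a chance share of 0.794%. The share of higher genes was 44.7% as measured, 55.2% (1063 higher, 864 lower) with median-of-ratios scaling and 55.1% (587 and 478) without mitochondrial, haemoglobin and antibody genes. Without peritoneal replicate 2 the number was 528, without pleural replicate 4 it was 529, without pleural replicate 5 696, without pleural replicate 3 731 and without peritoneal replicate 5 814. The 2-fold number fell to 94 without peritoneal replicate 2 and to 98 without pleural replicate 4. Peritoneal replicates 2 and 5 stood apart on the first principal component (46.7 and 57.4, other peritoneal libraries at most 11.7). Without both 485 genes passed (139 higher, 346 lower), 72 of them at least 2-fold. Other splits gave at most 53 called genes.

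Of the single genes chosen in advance, B2m, H2-K1, Mki67, Ptprc and Cd274 did not pass in sorted cells and Msln passed in peritoneal against subcutaneous cells. B2m, the light chain of class I molecules, measured 1818±377 TPM in pleural, 1695±263 in peritoneal and 1806±328 in subcutaneous cells (n = 5 each) and did not pass (adjusted p = 0.999, 0.737 and 0.735). Nor did the class I gene H2-K1 (adjusted p = 0.647, 0.397 and 0.898) or the proliferation marker Mki67 (adjusted p = 0.997, 0.934 and 0.906). Wt1 was not tested in sorted cells. Cd274 did not pass in peritoneal cells (4.05±2.19 against 11.1±4.11 TPM, log2FC -1.32, adjusted p = 0.0546). It was called without peritoneal replicate 1 (adjusted p = 0.0361), without pleural replicate 1 (0.0209) or without pleural replicate 2 (0.0492). In pleural cells Cd274 did not pass (5.67±5.30 TPM, log2FC -1.10, adjusted p = 0.304) except without pleural replicate 1 (log2FC -1.48, adjusted p = 0.0389), and between the serosal sites it did not pass (adjusted p = 0.764). Msln rose in peritoneal cells from 166±16.3 to 241±37.9 TPM (log2FC 0.52, SE 0.16, adjusted p = 0.0459), a call lost in 12 alternative fits, for instance without peritoneal replicate 2 (adjusted p = 0.124). Msln did not pass in pleural cells (249±64.4 TPM, log2FC 0.54, adjusted p = 0.128) except without pleural replicate 1 (log2FC 0.69, adjusted p = 0.00929).

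Leukocyte RNA in sorted cells was tested by exact permutation. Ptprc differed by log2FCs of -0.90 in pleural (exact permutation p = 0.333) and -1.26 in peritoneal cells (p = 0.159) against subcutaneous cells and by 0.35 between them (p = 0.222). The pan-leukocyte mean gave -1.11 (exact permutation p = 0.103), -1.13 (p = 0.103) and 0.02 (p = 0.937). None of these passed with all libraries, but the pleural difference from subcutaneous cells had an exact permutation p = 0.0397 without subcutaneous replicate 3 and 0.0317 without subcutaneous replicate 5. The peritoneal difference had an exact permutation p = 0.0238 without subcutaneous replicate 5.

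Whole tumours and sorted cells shared part of their site differences over the 11952 genes tested in both. Against the subcutaneous site, 84 genes were called in the same direction in pleural samples of both kinds (35 higher, 49 lower, 0 opposite), Inmt, Car9, Postn, Tnc, Ccl11 and Cxcl14 among them. Independent calls would give 5.10 higher and 4.31 lower, and the fold changes correlated with r = 0.47 and Spearman rho = 0.25. The 84 became 54 and 52 without subcutaneous sorted replicates 1 and 2 in turn and 32 without both. In peritoneal samples 229 were shared (110 higher, 119 lower, with 52.7 and 20.3 by independence, r = 0.44 and rho = 0.22), including Ccl11 and Cxcl14, and 10 went in opposite directions. The 229 became 143 and 149 without subcutaneous tumour replicates 2 and 5 in turn and 102 with the replicate number as a block. Between the serosal sites 3 were shared, Bcl6, Plk2 and Ccn2, all higher in pleural samples (r = 0.31, rho = 0.40). With single tumours left out these 3 became 0 (subcutaneous 3 or 5, peritoneal 1, 2, 3 or 7, pleural 1, 2, 4 or 5). They became 1 without subcutaneous or peritoneal replicate 4, 16 without pleural replicate 3, and 0 with a pseudocount of 0.1, without a filter, with the stricter filter or under the block. Mouse names recur in both kinds of sample, but whether the animals did is not given.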

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

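Explanations in this part were tested after the fits without the doubted libraries had been seen. Exact permutation tests used list means. Splits were planned beforehand.

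Lower matrix genes in serosal sorted cells could reflect leukocyte RNA in subcutaneous replicates 1 and 2, other host stroma in the subcutaneous gate, or the cancer cells themselves. For the 9 matrix genes called at both sites (such as Postn, Tnc and Loxl2) the median log2 fold change was -1.71 in pleural and -1.89 in peritoneal cells, and -1.64 and -1.82 without both libraries. Of the whole list of 29 matrix genes, 7 in pleural and 10 in peritoneal cells were called lower without them, which argues against leukocyte RNA as the whole cause. Endothelial genes fell in the same cells, by a median log2 fold change of -1.06 in pleural and -1.57 in peritoneal cells, and of -1.10 and -1.61 without both libraries, and 5 and 6 of 13 fibroblast genes fell there (4 and 5 without both libraries). RNA of other host stroma therefore stays open, and a change within the cancer cells was not separated from it.

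Lower immediate early and heat shock genes in peritoneal sorted cells could come from replicates 2 and 5, which stand apart, from handling during sorting, or from the site. Without those libraries the median log2 fold change went from -0.80 to -0.58 (exact permutation p = 0.107 against 0.0238), so their part is undecided. Unsorted peritoneal tumours gave a median of -0.25 for that list (list mean 4.61 against 4.77, exact permutation p = 0.0159). List means of sorted cells lay further apart (6.82 against 7.81) and whole tumours hold host cells, so handling stays open. RNA quality was not tested and stays open: peritoneal sorted cells also had a mitochondrial share of 2.91 to 4.50% against 5.6 to 6.63%, and more of the nuclear RNA Neat1, picked after its values were seen (33.0±15.4 against 14.3±1.81 TPM, log2 fold change 1.05, adjusted p = 0.00972).

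Negative medians of the macrophage and type I interferon lists in serosal sorted cells could be leukocyte RNA of subcutaneous replicates 1 and 2, where C1qa reached 266 and 174 TPM. With all libraries the mean of the macrophage list did not pass in pleural (exact permutation p = 0.222) or peritoneal cells (exact permutation p = 0.159), nor did that of the interferon list in pleural cells (exact permutation p = 0.0635), whereas it was lower in peritoneal cells (exact permutation p = 0.00794). The macrophage median log2 fold change went from -1.40 to -0.041 in pleural and from -1.46 to -0.28 in peritoneal cells without both libraries, as leukocyte RNA would give, but there was no passing difference to explain. For type I interferon genes the median went from -0.78 to -0.54 in pleural (exact permutation p = 0.232) and from -0.90 to -0.68 in peritoneal cells (exact permutation p = 0.0536), so the explanation stays open there.

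Splits that exchange libraries between groups tested the counts. In 100 splits with the real one included, gene counts as high as the real one occurred in 1 for pleural against subcutaneous whole tumours (1927, highest other 191; at least 2-fold 187, highest other 58), peritoneal against subcutaneous whole tumours (1831, highest other 4; 266 and 4), and the genes shared by the serosal sites (944, highest other 0). The same held in sorted cells, with 203 against 60 (at least 2-fold 118 against 16), 1369 against 165 (317 against 6), 1231 against 53 (152 against 36) and 155 shared against 1. Pleural against peritoneal whole tumours gave 8 in 2 splits (at least 2-fold 4, highest other 1). Counts of called lists were as high in 28, 8 and 16 splits for whole tumours (23 against 34, 29 against 31 and 25 against 32) and in 41, 17 and 45 splits for sorted cells (15 against 27, 19 against 25 and 12 against 21). No other split reached the gene counts, apart from the 8, but some reached the list counts. Splits cannot test causes that go with site.

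Values far from the others of their group were found in 48 of 609 groups, where chance gives 30.45; sorted subcutaneous replicates 1 and 2 held 7 and 5 of them. In whole tumours the genes, as log2(TPM + 1), were Cd209a high in peritoneal replicate 7 at 1.51, Cd209g low in subcutaneous replicate 1 at 2.40, Cd8a low in subcutaneous replicate 2 at 3.27 and in pleural replicate 1 at 2.86, and Pdcd1 low in the same 2 tumours at 2.53 and 2.69. Antibody segments were Igkv1-88 high in pleural replicate 2 at 4.33, an Igkv16 segment high in peritoneal replicate 7 at 6.35 and Igkv4-53 high in subcutaneous replicate 4 at 0.51. Mup10 was low in subcutaneous replicate 3 at 1.57 and high in peritoneal replicate 1 at 0.75 and pleural replicate 4 at 0.95, and Mup22 low in subcutaneous replicate 3 at 0.71 and high in peritoneal replicate 7 at 0.46. Pleural replicate 5 stood out for muscle, with Myh4 at 2.67, Tnnc2 at 6.32 and Tnnt3 at 6.41. In peritoneal replicate 4 Wt1 was low at 2.03 and Zfp969 high at 1.28. List means that stood out were cholesterol synthesis (pleural replicate 1, low, 5.57), extracellular matrix (peritoneal replicate 2, high, 6.79), Hippo targets (subcutaneous replicate 2, low, 4.40), mesothelium (pleural replicate 2, high, 3.50) and type 2 and migratory dendritic cells (peritoneal replicate 7, high, 3.33).

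In sorted cells subcutaneous replicate 1 was high for Cpxm1 at 5.62, Cxcl14 at 6.86, Mmp2 at 5.63, Mmp3 at 5.05, Oasl1 at 3.85, Pi16 at 2.91 and the interferon gamma list at 6.10. Subcutaneous replicate 2 was low for Bhlhe40 at 5.13, Egr1 at 9.46, Skil at 4.39 and the TNF and NF-kB list at 5.30, and high for oxidative phosphorylation at 7.77. Peritoneal replicate 2 was high for Acsm3 at 4.65, Hba-a1 at 6.03 and the red cell list at 4.93. Peritoneal replicate 3 was high for Pi16 at 1.65 and Sgk1 at 4.57 and low for Plk1 at 5.45, and peritoneal replicate 5 was low for Mki67 at 4.90. Pleural cells gave Calcb low at 2.35 and Eno1 low at 9.81 in replicate 1, Inmt low at 1.93 in replicate 2, and in replicate 3 Egr2 low at 3.16 and the Hippo list high at 5.46.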

How the results depend on the processing

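The fits without doubted libraries, named below, were chosen only after the data had been seen. Apart from fits that leave out a single library, 2150 of the values for named genes kept their side of the threshold and their direction, 91 lost a call, 11 gained one and 8 reversed; for lists these numbers were 1345 unchanged, 292 weaker and 3 reversed. Which results fall below the limit set by sequencing depth is unknown. For every value below that differs from the report the cause was not tested, except that fewer libraries or genes enter some fits by construction and that a threshold of 0.01 must give fewer calls.

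In pleural against subcutaneous whole tumours 1136 genes were called without a filter and 401 at adjusted p below 0.01, and 307 changed at least 2-fold with a pseudocount of 0.1 and 112 with the stricter filter. For peritoneal against subcutaneous whole tumours these numbers were 1164, 477, 408 and 147. Camera with an estimated correlation called 0 lists in each of the 6 comparisons, and fry called 7 and 9 lists in these 2 and 0 between pleural and peritoneal whole tumours. Genes shared by the serosal sites in whole tumours were 536 without a filter.

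Between pleural and peritoneal whole tumours the 8 genes became 0 with a pseudocount of 0.1, with the stricter filter and at adjusted p below 0.01, 5 with robust empirical Bayes and 21 without pleural tumours 3 and 5. Genes with a 2-fold change became 0 with a pseudocount of 0.1 and with the stricter filter, 2 without a filter and 7 without pleural tumours 3 and 5. The skeletal muscle list turned direction without those tumours (median -0.095).

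In pleural against subcutaneous sorted cells 107 genes were called with the stricter filter, 406 with arrayWeights and 106 at adjusted p below 0.01; 60 and 56 changed at least 2-fold with the stricter filter and without subcutaneous sorted libraries 1 and 2, and fry called 3 lists. The cholesterol synthesis list turned direction without those libraries (median -0.016). In peritoneal against subcutaneous sorted cells 2486 genes were called with quantile normalization and 432 at adjusted p below 0.01, and 202 and 204 changed at least 2-fold with the stricter filter and without peritoneal sorted libraries 2 and 5. Between pleural and peritoneal sorted cells 1927 were called with median-of-ratios scaling, 2229 with quantile normalization, 691 with only the 2 sites in the fit and 187 at adjusted p below 0.01; 72 changed at least 2-fold without those libraries, and fry called 6 lists. The oxidative phosphorylation list turned direction in its test without them (median -0.0365).

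Genes shared by the serosal sites in sorted cells were 76 with the stricter filter, 233 with arrayWeights and 64 without subcutaneous sorted libraries 1 and 2. Those shared by whole tumours and sorted cells became 52 with the stricter filter, 175 with arrayWeights and 32 without those libraries for pleural against subcutaneous; 143 without a filter and 397 with arrayWeights for peritoneal against subcutaneous; and 1 with robust empirical Bayes and 9 without pleural tumours 3 and 5 between the serosal sites.

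Of the genes called with all libraries, 1539, 1781 and 4 stayed called in the same direction in whole tumours without pleural tumours 3 and 5, of 2389, 2292 and 21 called then (comparisons in the order above). In sorted cells 64, 768 and 1082 stayed of 70, 917 and 1179 without subcutaneous libraries 1 and 2, and 198, 569 and 369 of 262, 741 and 485 without peritoneal libraries 2 and 5.

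The replicate numbers, taken from the mouse names, do not pair the samples: deviations of same-numbered libraries correlated with r from -0.38 to 0.26 in whole tumours and from -0.30 to 0.35 in sorted cells, and 3 of 16 and 5 of 15 libraries correlated best with their own number. With the replicate number as a block 849, 656 and 0 genes were called in whole tumours (0 with a 2-fold change between pleural and peritoneal), 359 were shared by the serosal sites, and 102 were shared with sorted cells for peritoneal against subcutaneous. Foxp3 turned direction in pleural against peritoneal whole tumours under the block (-0.0253), and the calls of Igkv6-23, Tnnt3, Klrb1c and Cd53 were lost, as were those of Pvalb, Myl1 and Ckm.

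Reversals concerned values near 0 that did not pass. In pleural against subcutaneous sorted cells B2m was -0.0381 with quantile normalization, -0.00142 without mitochondrial, haemoglobin and antibody genes and -0.0739 with arrayWeights, and Mki67 was 0.0109 with median-of-ratios scaling. In pleural against peritoneal sorted cells Cd274 was -0.136 with arrayWeights and -0.0312 without peritoneal libraries 2 and 5, Msln was -0.0102 with quantile normalization, and the pan-leukocyte mean was -0.0506 with the stricter filter, -0.0165 with quantile normalization, -0.0213 without subcutaneous libraries 1 and 2 and -0.0527 without peritoneal libraries 2 and 5.

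With a single library left out, genes called ranged from 748 (without subcutaneous replicate 2) to 2226 (without pleural replicate 3) in pleural against subcutaneous whole tumours, those with a 2-fold change from 119 to 234. In peritoneal against subcutaneous whole tumours they ranged from 896 (without subcutaneous replicate 2) to 2178 (without pleural replicate 3), and between pleural and peritoneal whole tumours from 0 to 33 (without pleural replicate 3). Genes called against subcutaneous at both serosal sites ranged from 361 to 1109 in whole tumours and from 99 (without subcutaneous replicate 1) to 176 in sorted cells. Those shared by whole tumours and sorted cells ranged from 52 to 116 for pleural against subcutaneous, from 143 to 278 for peritoneal against subcutaneous (both highest without pleural replicate 3 of the whole tumours) and from 0 to 16 between the serosal sites. In sorted cells genes called ranged from 118 (without subcutaneous replicate 2) to 268 (without pleural replicate 1) for pleural against subcutaneous and from 752 (without subcutaneous replicate 5) to 1610 (without peritoneal replicate 1) for peritoneal against subcutaneous. Between pleural and peritoneal sorted cells they ranged from 528 (without peritoneal replicate 2) to 1420 (without peritoneal replicate 1), and those with a 2-fold change from 94 to 210 (without peritoneal replicate 3).

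Named genes that turned direction with a single library left out did not pass with all libraries. In whole tumours Cd8a ranged from -0.25 to 0.094 in pleural and from -0.20 to 0.043 in peritoneal against subcutaneous tumours and from -0.13 to 0.13 between them, Cd274 from -0.35 to 0.032 in peritoneal against subcutaneous tumours, and Foxp3 from -0.041 to 0.064 in pleural against peritoneal tumours. In sorted cells B2m ranged from -0.075 to 0.092 in pleural and from -0.17 to 0.0025 in peritoneal against subcutaneous cells, and Mki67 from -0.11 to 0.062 and from -0.082 to 0.30. Between pleural and peritoneal sorted cells Mki67 ranged from -0.32 to 0.066, Cd274 from -0.16 to 0.46, H2-K1 from -0.036 to 0.12 and Msln from -0.082 to 0.16. The pan-leukocyte mean of sorted cells ranged from -1.44 (without subcutaneous replicate 5) to -0.77 in pleural and from -1.46 (without subcutaneous replicate 5) to -0.75 in peritoneal against subcutaneous cells, and from -0.12 to 0.12 between them.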

Other observations

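The explanation tested in this part was chosen only after the results had been seen.

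Some tissue and macrophage genes not described so far also differed between peritoneal and subcutaneous whole tumours. Of 5 mammary epithelial genes 4 rose and 0 fell (4 and 1 over the list alone, median log2 fold change 1.52, adjusted p = 0.404 with an estimated correlation), and of 14 genes of serosal resident macrophages 5 rose and 1 fell (7 and 1 over the list alone, median log2 fold change 0.41, adjusted p = 0.630 with an estimated correlation). In pleural against subcutaneous whole tumours 8 of 24 genes of the unfolded protein and integrated stress response rose and 0 fell (11 and 0 over the list alone, median log2 fold change 0.23, adjusted p = 0.645 with an estimated correlation), a number of 3 without subcutaneous replicate 2, 5 without subcutaneous replicate 3 and 4 without pleural replicate 2 or without pleural replicate 4. In peritoneal against subcutaneous sorted cells 6 of 16 complement and coagulation genes fell and 0 rose (9 and 0 over the list alone, median log2 fold change -0.62, adjusted p = 0.290 with an estimated correlation).

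A hypothesis of this re-analysis was that the called decreases among leukocyte genes of serosal whole tumours reflect a smaller share of host cells, although the pan-leukocyte mean did not pass (exact permutation p = 0.199 in pleural and 0.0714 in peritoneal tumours) and some B cell and plasma cell genes rose in peritoneal tumours. If it held, Xist, expressed by the female hosts, could be lower there. Xist was instead higher by 0.43 log2 units in pleural (exact permutation p = 0.0887) and by 0.30 in peritoneal tumours (exact permutation p = 0.294). Neither difference passed, so the hypothesis stays undecided. Xist is not among the genes of the sorted cell table, from which genes below about 1 TPM had been removed.

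Muscle RNA varied between libraries of a site: the mean of the skeletal muscle list, as log2(TPM + 1), was 3.97 ± 1.23 in subcutaneous (SD, n = 5), 0.85 ± 0.064 in peritoneal (n = 5) and 1.74 ± 1.71 in pleural tumours (n = 6). Sorted pleural replicate 5 held the lung epithelial transcript Sftpc at 31.9 TPM.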
